A study of Mus musculus with 6 samples.

How the data were processed

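Livers of 6 male C57BL/6 mice, 6 weeks old, were profiled on Affymetrix mouse arrays with 1 array per mouse. Per the labels, 3 mice carried a liver-specific conditional knockout of p14 (KO 1 to KO 3) and 3 were controls (WT 1 to WT 3). p14 is the protein product of Lamtor2, an adaptor on late endosomes that is part of the Ragulator complex. Each mouse counts as a separate biological replicate, per the labels. Per the labels' protocols, 1 ug of column-purified total RNA was converted to biotinylated target with the manufacturer's single-cycle kits.

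The deposited values were log2 expression levels per probe set, made by the authors with R 2.9.1 and GCRMA 2.16.0 per the submitters' processing notes. GCRMA subtracts a background estimated from probe sequence, normalises across arrays and summarises the probes of a set. Further settings were not given in the sources used here. The log2 scale was inferred from the deposited values, which ran from 2.185 to 16.327. Of all values, 28.9% lay at the lowest value, so differences among dim probe sets carry little information, and background correction can enlarge the difference of a gene that reaches the lowest values in only 1 group. No detection calls, scan dates or slides were analysed here. The number of arrays limits the precision.

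The table held 45101 probe sets, of which 64 were manufacturer controls and were used only as quality measures. The annotation of the array platform paired 34945 probe sets with a single gene symbol, 932 with several and 9160 with none listed. Probe sets with several symbols named no gene. The Entrez identifiers of 34754 probe sets were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. Among the 18193 genes, each was represented by the probe set with the highest mean over all 6 arrays. Genes with a log2 value of at least 4 on at least 3 of the 6 arrays were kept, whichever group the arrays belonged to. This left 10009 genes and set aside 8184.

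KO was compared with WT in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided moderated test, no covariates). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All differences are KO minus WT on the log2 scale. Where every array of a group lay below 4, the fold is given as at least the brighter group's mean against that level. Single measures were compared with an exact two-sided permutation test, whose smallest p with 3 against 3 arrays is 0.1. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, for lists with at least 5 measured genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The 38 lists covered late-endosomal and liver pathways and markers of the cell types a liver sample can hold, and 724 of their 821 entries had a probe set. Members were counted with p adjusted over all genes and adjusted over the list alone.

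The main tests, the lists and most alternatives were fixed before the data were examined. So was the rule for naming genes. Lamtor2 came first, followed by up to 12 called genes with non-overlapping groups in each direction, filled up with the smallest unadjusted p. Each list then gave up to 4 called members, or up to 2 members with the smallest p where none was called. Predicted genes and clone names were skipped in the text, and not every list member so picked is given there. Genes named outside this rule are identified where they appear.

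The gene test and camera were tested on simulated data for the comparison of KO with WT over 10009 genes. The gene test recovered 42% of 50 genes changed 1.5-fold, 78% of those changed 2-fold, 98% at 4-fold and 96% at 8-fold, with 2 false calls. Camera recovered the 1 shifted list and called 0 others. The simulated genes varied independently and had no lowest value, so these rates need not hold for correlated genes or dim probe sets. Alternatives covered the filter, the normalisation, the handling of background and of several probe sets per gene, the variance model, array weights, a replicate block, each array left out in turn and the kind of list test. A further 3 were added after the data were seen. Figures were drawn with matplotlib 3.10.9.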

Results

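Expression in the liver was measured on 6 arrays, 3 from p14 knockout mice and 3 from control mice. On each array 43.5% to 43.9% of probe sets had a log2 value of at least 4, and between 9942 and 10122 genes were at that level. The values had been normalised across arrays, so this likeness does not compare the arrays before processing. The first principal component held 49.5% of the variance. On it the WT arrays lay between 14.19 and 21.55, KO 1 and KO 2 at -30.39 and -22.27, and KO 3 at -2.58. KO 3 correlated with the other KO arrays at a mean r of 0.986 over genes and with the WT arrays at 0.987.

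Lamtor2, the targeted gene, was lower on every KO array. Its brighter probe set (Entrez gene 83409) measured 10.13 ± 0.06 in KO and 11.32 ± 0.03 in WT (log2, SD, n = 3 each), so that KO livers held 43.8% of the WT signal. The difference of -1.19 passed the threshold in limma (Benjamini-Hochberg adjusted p = 0.0104), and the exact permutation p was 0.1, the smallest this design allows. The other probe set of Lamtor2 lay near background in both groups, at 2.27 in KO and 2.52 in WT. Where these probes lie relative to the deleted part of the gene was not analysed here, so the signal that stayed in KO livers does not measure the remaining intact transcript. The limma adjusted p of Lamtor2 was 0.0691 without KO 2, 0.114 without WT 1, 0.114 without WT 2 and 0.0505 without WT 3, while the difference stayed between -1.23 and -1.17.

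The comparison of KO with WT asked which other liver transcripts differ when p14 is missing. Several of the called genes act in cell division. Top2a, the topoisomerase of replicating chromosomes, fell from 6.43 ± 0.14 in WT to 3.56 ± 0.42 in KO (log2, SD, n = 3 each), where 1 of the 3 arrays reached 4. Aurka, a mitotic kinase, was at least 2.02-fold lower and Kif20a, a kinesin of cell division, at least 1.67-fold lower. Cdkn3, a phosphatase of cyclin-dependent kinases, and Nuf2, part of the kinetochore complex that holds chromosomes to the spindle, fell as well. Crym, a thyroid hormone-binding protein, was at least 13.2-fold lower and had the lowest log2 fold change of the called genes. F3, which encodes tissue factor, the starter of coagulation, rose by 0.89, and A1cf, the partner of the apolipoprotein B mRNA editing enzyme, rose by 1.82.

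In total 17 of 10009 genes changed at an adjusted p under 0.05 in limma, of which 2 rose and 15 fell. By the fitted difference, 12 of these differed at least 2-fold, 1 higher and 11 lower. For Kif20a and Nuf2, counted among the 11, the bounds were only 1.67-fold and 1.47-fold. Every one of the 17 had its 3 KO arrays on one side of its 3 WT arrays. Groups did not overlap for 2055 genes, or 20.5%, where chance gives 10%. At an unadjusted p under 0.05 there were 1447 genes, 432 higher and 1015 lower, against 500.5 by chance. Both chance values are averages, and genes that vary together can take a single split of the arrays well past them. Other splits were not counted in these ways, so the size of either excess was not tested.

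The limma adjusted p was 0.00114 for Aurka, 0.0163 for Kif20a, 0.0275 for Top2a, 0.0275 for Cdkn3 and 0.0163 for Crym. In 7 called genes all 3 KO arrays lay below a log2 value of 4, so only a bound on the fold can be given. Besides Aurka, Kif20a and Crym, the KO level was at least 2.29-fold lower for Cdkn3, at least 1.47-fold lower for Nuf2, at least 2.03-fold lower for Trim59, an E3 ligase family member, and at least 5.21-fold lower for Tifa, an adaptor of inflammatory signalling. For Crym the 3 KO values were tied at 3.67, against 7.72 ± 0.53 in WT (SD, n = 3). Aurka measured 2.66, 2.763 and 2.66 on the KO arrays. Tied or very low values can understate the spread between mice, so the small p of such genes does not make them the most secure.

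Lyve1, a hyaluronan receptor of liver sinusoidal and lymphatic endothelium, fell from 8.76 ± 0.10 to 7.44 ± 0.18 (SD, n = 3, a difference of -1.32 with a limma adjusted p of 0.0353). Thbd, the endothelial anticoagulant thrombomodulin, fell by 0.95 (limma adjusted p = 0.0353). Camsap3, which binds microtubule minus ends, fell by 1.06. Pltp, the phospholipid transfer protein of plasma, fell by 0.92, Hacd4 by 0.75 and Spc24, of the same kinetochore complex as Nuf2, by 0.54; these 3 lay outside the naming rule and were chosen after their values were seen.

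No further gene was called as higher in KO. The genes with the smallest p among those higher in KO were Angptl4, an inhibitor of lipoprotein lipase, at 0.50 (limma adjusted p = 0.0655) and Etfbkmt at 1.18 (0.0655 by limma). The differences were 0.62 for Tm9sf4, 0.72 for Rassf5, 0.73 for Agap1, 0.64 for Dnmbp and 0.63 for Slc30a7, and Pik3c2g was at least 4.20-fold brighter. A further probe set past the filter went the other way for Slc30a7, at -0.52, and showed -0.04 for Agap1. For Tm9sf4, Rassf5 and Dnmbp it lay at 0.49, 0.94 and 0.73. Among all named genes, 45 of 56 such further probe sets had the same direction as the one used. Hddc3 measured 7.33 in KO and 4.05 in WT, where 2 of 3 arrays reached 4, and Carmil1 measured 6.06 in KO and 3.64 in WT, where 1 of 3 did. The limma adjusted p of these genes lay between 0.0842 and 0.165.

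The number of called genes depended on which arrays were included. It was 6 without KO 1, 1 without KO 2, 140 without KO 3 (26 higher and 114 lower), 1 without WT 1, 1 without WT 2 and 5 without WT 3. With no filter on dim probe sets it was 3, and it was 3 with an ordinary two-sample test in place of the moderated one.

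**Figure D1:**
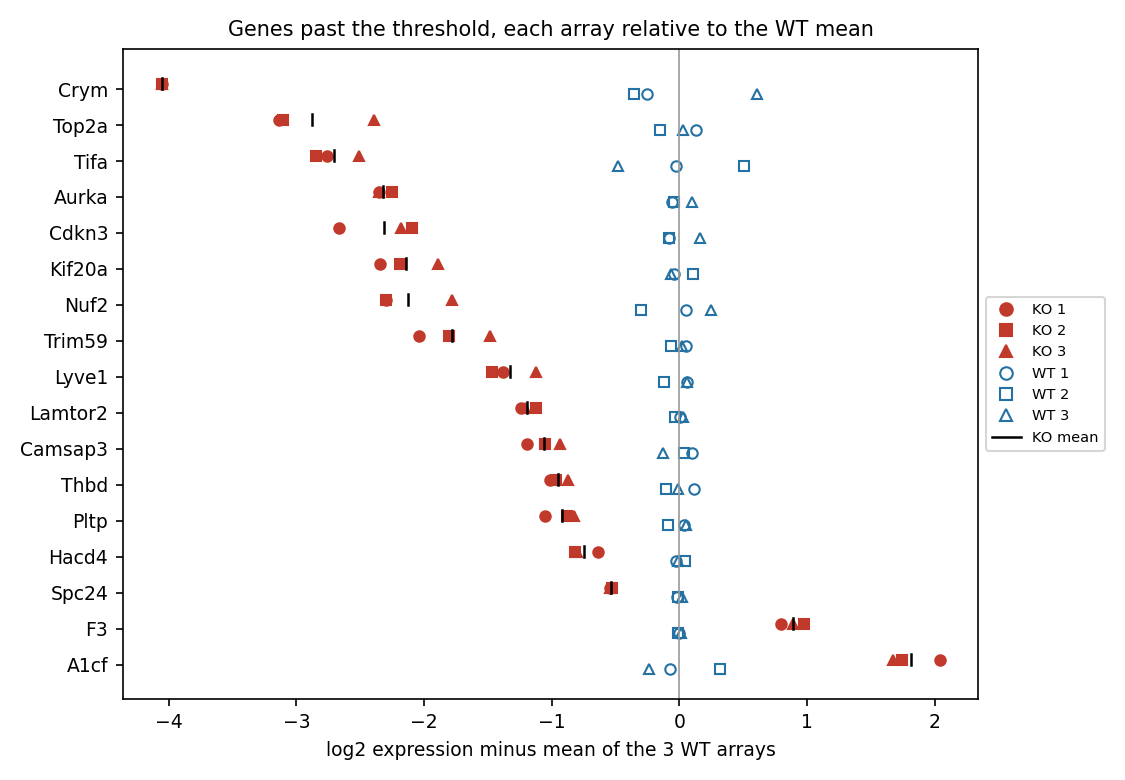
Log2 expression of the 17 called genes on each array, minus the mean of the 3 WT arrays (horizontal axis, log2 units). Filled symbols are KO arrays, open symbols WT arrays and the bar the KO mean, and KO and WT lie apart for each gene, though for 7 genes with all KO arrays below a log2 value of 4 the distance bounds no fold.

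Among the gene lists, male-biased genes had the mean furthest from 0, at 2.02 against -1.75 for cell cycle and mitosis. That mean includes Slco1a1 at 8.06 and Cyp4a12a at 5.49, and the male-biased median was 0.89. The median furthest from 0 was that of cell cycle and mitosis. Of 23 measured members 22 were lower in KO, with a median of -2.01, and 3 fell when adjusted over all genes while 19 fell when adjusted over the list alone. Among members not called over all genes, Mki67, the proliferation marker Ki-67, measured 4.65 in KO and 7.92 in WT, and Ccnb2, a mitotic cyclin, 3.42, with 1 of 3 KO arrays at 4 or above, and 7.13; both were chosen after their values were seen. Camera placed the list past the threshold (limma, adjusted p = 1.83e-15), and fry did too (limma, adjusted p = 0.0339), but camera did not with an estimated correlation (limma, adjusted p = 0.781). With values floored at 4, which bounds the dim genes, the median was -1.21. List means were 5.15, 5.37 and 6.13 on the KO arrays and 7.20 to 7.41 on the WT arrays. Between the same groups the signal of the 18S rRNA controls was 0.803 higher in KO, and macrophage and endothelial markers had medians of -0.89 and -0.30. The pyruvate carboxylase 3 prime minus 5 prime measure, used here for RNA integrity, differed by -0.95, being smaller on the KO arrays.

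Markers of macrophages, endothelial cells and stellate cells were lower in KO. Kupffer cell and macrophage markers had a median of -0.89, 18 of 20 members were lower, and 11 fell when adjusted over the list alone while 0 fell over all genes (camera in limma, adjusted p = 1.59e-06, but adjusted p = 0.781 with an estimated correlation). Lysozyme transcripts measured 10.10 in KO and 11.24 in WT for Lyz2, whose probes can share targets with Lyz1, and Marco, a scavenger receptor chosen after its values were seen, 5.49 and 8.23. Liver endothelial markers had a median of -0.30, with 18 of 21 lower, 1 of them, Lyve1, fallen over all genes and 7 adjusted over the list alone (camera in limma, adjusted p = 0.000173, but adjusted p = 0.781 with an estimated correlation). Stellate cell and fibrosis markers had a median of -0.45, with 20 of 21 lower, 0 fallen over all genes and 2 adjusted over the list alone (camera in limma, adjusted p = 0.000349, but adjusted p = 0.781 with an estimated correlation). Sparc, a matrix glycoprotein, differed by -0.54 and Tgfb1 by -0.65, neither called over all genes. The stellate median was -0.24 without WT 2, the array with the highest stellate list mean, 9.18, and with skeletal muscle transcripts 9.14 above the mean of the other arrays. Hepatocyte secreted proteins had a median of -0.04 and lymphocyte markers of 0.06, and neither list passed. Only 5 of 24 lymphocyte markers were measured, 4 higher and Ccl5 lower at -1.11, with list means of 4.755 to 5.233. These few dim markers do not show that lymphocytes were unchanged. The macrophage, endothelial and stellate lists moved opposite to the 18S rRNA controls, which were 0.803 higher in KO.

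Immune response genes formed 3 of the lists past the threshold. Antigen presentation by MHC class II had a median of -0.95, with 6 of 6 members lower and 4 fallen when adjusted over the list alone, against 0 over all genes (camera in limma, adjusted p = 0.000605, but adjusted p = 0.781 with an estimated correlation). Cd74, the invariant chain, measured 9.29 ± 0.32 in KO and 10.40 ± 0.18 in WT (SD, n = 3 each). The macrophage markers, with a median of -0.89, and the 18S rRNA controls, 0.803 higher in KO, differed between the same groups. Interferon-stimulated genes had a median of -0.33 with 22 of 23 lower and 0 fallen by either adjustment (camera in limma, adjusted p = 0.00378, but adjusted p = 0.781 with an estimated correlation), among them Gbp2 at -2.05 and Cxcl10 at -1.55. Without WT 2 this list did not pass (limma, adjusted p = 0.397), and its median was -0.21 without KO 1 and -0.53 without KO 3. WT 2 is the array with skeletal muscle transcripts. Acute-phase proteins went the other way, with a median of 0.27, 20 of 23 higher and 0 risen by either adjustment (camera in limma, adjusted p = 0.000441, but adjusted p = 0.781 with an estimated correlation). The acute-phase median was 0.11 without KO 1, 0.18 without KO 2 and 0.41 without KO 3. Acute-phase list means were 13.707, 13.62 and 12.548 on KO 1, KO 2 and KO 3. On the same arrays the 18S rRNA controls, also highest on KO 1 and KO 2, measured 9.245, 9.115 and 8.501. Members named by the rule were Itih4 at 0.32 and Steap4 at -0.30. Serum amyloid transcripts, chosen after their values were seen, reached 15.83 and 15.78 for Saa1 on KO 1 and KO 2, against 12.22 on KO 3 and 10.83 to 12.03 on the WT arrays. KO 1 and KO 2 also reached 15.69 and 15.53 for Saa2, and 14.34 and 13.64 for Lcn2, the iron-sequestering lipocalin, against 10.02 for Saa2 and 8.43 for Lcn2 on KO 3. Probes of Saa1 and Saa2 can share targets.

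Male-biased liver genes had a median of 0.89, with 9 of 10 higher, 4 risen when adjusted over the list alone and 0 over all genes (camera in limma, adjusted p = 6.25e-05, but adjusted p = 0.781 with an estimated correlation). Slco1a1, an organic anion transporter, measured 12.10 ± 0.39 in KO and 4.04 ± 3.03 in WT (SD, n = 3 each), with WT values of 2.29, 2.29 and 7.53. Cyp4a12a, a fatty acid hydroxylase chosen after its values were seen, was at least 13.9-fold higher in the KO mean, with 11.29, 7.63 and 4.47 on the KO arrays and all WT arrays below 4. Cyp2u1 differed by 0.71. The 18S rRNA controls were 0.803 higher in KO between the same arrays. Female-biased liver genes had a median of -0.62 with 13 of 16 lower and did not pass (camera in limma, adjusted p = 0.138), with Prom1 at -2.52 and Cyp2c39 at -0.77. The female-biased list passed without KO 2 (camera in limma, adjusted p = 0.0421), without WT 3 (0.0469), with no filter (0.0178), with median centring (0.0176), with every probe set tested (0.0327) and with the mean of a gene's probe sets (0.0103). With all arrays and an estimated correlation it had an adjusted p = 0.781 in limma, and its median was -0.20 without KO 1 and -0.33 without WT 1.

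In all, 8 of the 33 lists large enough to test passed with camera, 2 higher and 6 lower in KO. With an estimated correlation 0 lists passed (limma, adjusted p = 0.781 for each of the 8, and 1 list at an unadjusted p under 0.05). The fry test for a shift in 1 direction called 1. In 5 of the 8 every KO list mean lay on one side of every WT list mean, with an exact permutation p of 0.1, which were cell cycle, macrophage, endothelial, MHC class II and male-biased genes. For acute-phase, interferon and stellate lists the arrays of the groups overlapped.

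**Figure D2:**
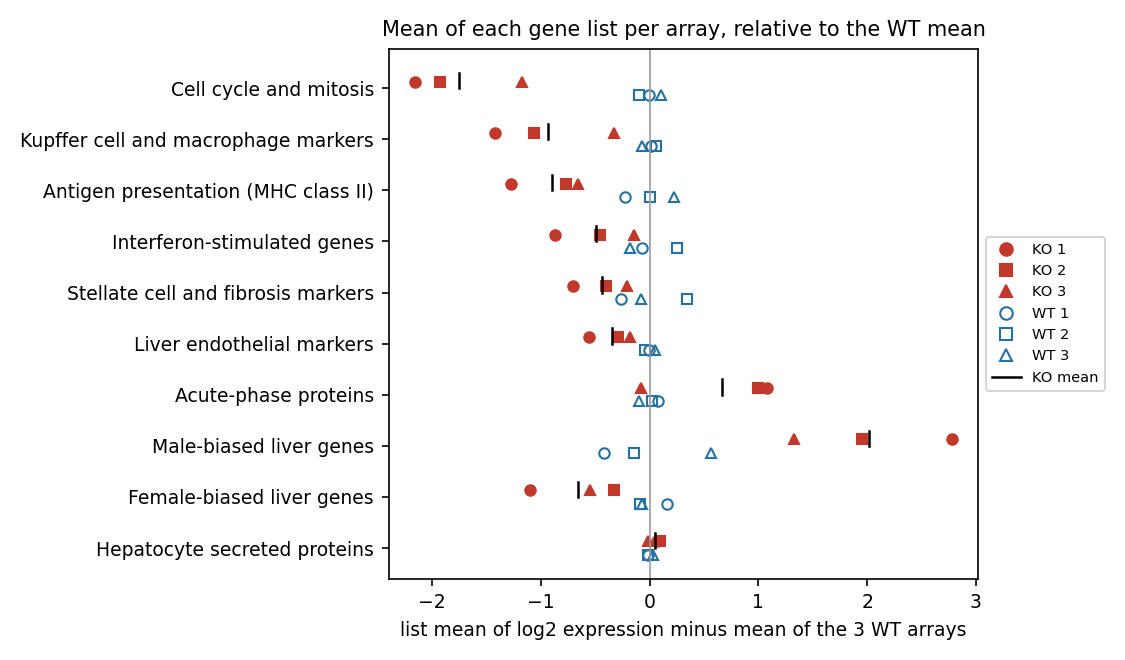
Mean log2 expression of 10 gene lists on each array, minus the mean of the 3 WT arrays (horizontal axis, log2 units), for the 8 lists past the camera threshold and for female-biased and hepatocyte genes. Filled symbols are KO arrays, open symbols are WT arrays and the bar is the KO mean; KO 3 is the KO array nearest to the WT mean for each of the 8 lists.

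Lists close to the known place of p14 did not pass as lists shifted in 1 direction. With fry's mixed test, for members changed either way, the limma adjusted p was 0.000278 for Ragulator components, which include Lamtor2. It was 0.00148 for autophagy, 0.0254 for ERK genes, 0.0496 for V-ATPase subunits, 0.0727 for lysosomal enzymes and 0.484 for trafficking. Lists further from p14 had low values too, such as 0.00122 for fatty acid oxidation. Ragulator, Rag and mTORC1 components had a median of 0.03 over 18 genes, of which Lamtor2 alone fell. The median was -0.01 for late endosome and lysosome trafficking, -0.08 for lysosomal enzymes and membrane proteins, -0.06 for V-ATPase subunits and 0.00 for autophagy genes, and 0 members were called in these. Their members with the smallest p were Mcoln1 at 0.48, Lgmn at -0.61, Atp6ap1 at -0.18 and Tfe3 at -0.47. Map1lc3b, next among the autophagy genes, was at 0.31. The lysosomal list passed with KO 3 and WT 2 both left out (camera in limma, adjusted p = 0.0479), a choice made after the data were seen, and its median was -0.03 without WT 3, -0.04 without WT 1, -0.05 without KO 1 and -0.12 without KO 3. The V-ATPase median was -0.09 without KO 1 or WT 1 and -0.10 without WT 2. ERK immediate-early and feedback genes had a median of -0.20, with 11 of 16 lower and 1, the ERK phosphatase Dusp6 at -1.27, fallen when adjusted over the list alone (camera in limma, adjusted p = 0.25). The ERK median was -0.09 without KO 1 and -0.31 without WT 3, and the list passed with every probe set tested (camera in limma, adjusted p = 0.00704). NRF2 targets had a median of -0.17 with 14 of 18 lower (camera in limma, adjusted p = 0.0946), and Gstm2 differed by -0.72; this list passed without KO 3 (camera in limma, adjusted p = 0.00309), with no filter (0.0126), with quantile normalisation (0.0131), with array weights (0.0483) and with KO 3 and WT 2 both left out (0.0211). With all arrays and an estimated correlation, the NRF2 and ERK lists each had an adjusted p = 0.781 in limma. Metabolic lists did not pass in the main test, with medians of -0.18 for fatty acid synthesis, -0.04 for fatty acid oxidation, 0.02 for bile acid genes, -0.07 for the urea cycle and -0.05 for oxidative phosphorylation. Fatty acid synthesis passed without KO 3 (camera in limma, adjusted p = 0.0321, median -0.39) and without both KO 3 and WT 2 (0.0211, median -0.44), and had a median of -0.10 without KO 1 or WT 3. The urea cycle passed without KO 2 (camera in limma, adjusted p = 0.034, median -0.16) and had a median of -0.03 without KO 1. Oxidative phosphorylation passed with no filter (camera in limma, adjusted p = 0.00475), with a median of -0.02 without KO 1 and -0.11 without KO 3. With all arrays and an estimated correlation, the lysosomal, fatty acid synthesis, urea cycle and oxidative phosphorylation lists each had an adjusted p = 0.831 in limma. With 1 array left out the medians of trafficking, autophagy, fatty acid oxidation and bile acid genes changed sign. Within p53 targets 3 of 13 members fell when adjusted over the list alone, among them Mdm2 at -0.39 and Zmat3, whose 3 KO values were tied at 5.80 against 6.23 ± 0.12 in WT (SD, n = 3). In the circadian clock list Nfil3, at 1.16, rose and Bhlhe40, at -0.65, fell by the same adjustment.

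RNA quality measures differed between the groups. The 18S rRNA control probe sets averaged 8.95 ± 0.40 in KO and 8.15 ± 0.35 in WT (log2, SD, n = 3 each, exact permutation p = 0.1), with every KO array above every WT array. The difference between 3 prime and 5 prime probe sets of pyruvate carboxylase was 3.55 ± 0.03 in KO and 4.50 ± 0.45 in WT (exact permutation p = 0.1). The same measure differed by -0.14 for beta-actin and -0.06 for Gapdh (exact permutation p = 0.3 for each). Poly-A spike-in controls averaged 0.21 higher in KO (exact permutation p = 0.3) and hybridisation spike-ins 0.07 higher (exact permutation p = 0.6). The 5 prime probe set rose more than the 3 prime one for DapX (0.262 against 0.122), LysX (0.278 against 0.185) and ThrX (0.31 against 0.1). For PheX it rose less (0.127 against 0.163). Spike-ins do not come from the liver, so such end differences need not measure the integrity of liver RNA. Skeletal muscle transcripts stood out on WT 2 alone, with a mean of 11.64 over 9 genes against 2.42 to 2.65 on the other arrays.

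**Figure D3:**
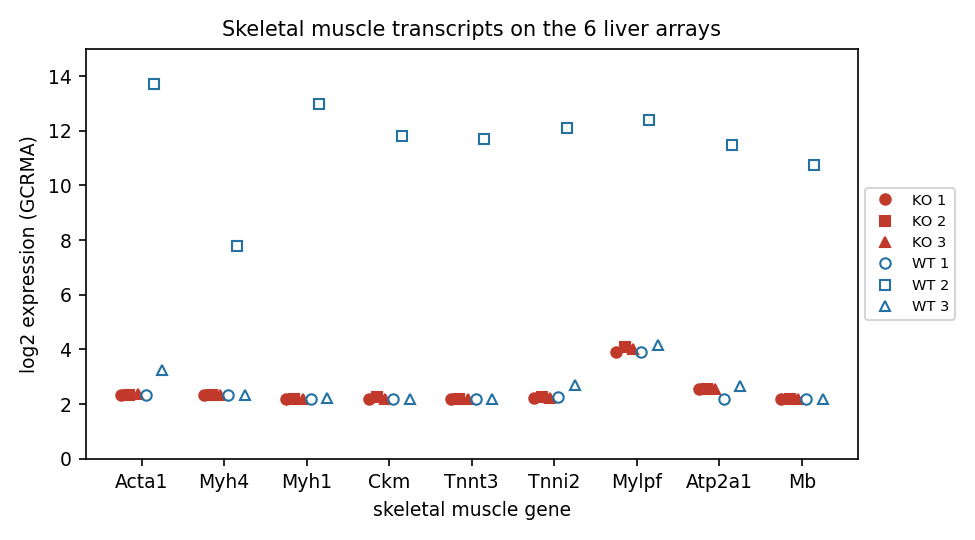
Log2 expression of 9 skeletal muscle genes (horizontal axis) on each of the 6 arrays (vertical axis, log2 units). Filled symbols are KO arrays and open symbols are WT arrays; WT 2 lies above all other arrays for every gene, at 13.72 for Acta1.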

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

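The tests of cell type shares and of WT 2 as a source of the cell cycle difference were chosen after the results were seen. Predictions of the other tests here were written before those tests were run. Patterns such as the muscle signal on WT 2 had come from these data, so tests of them were not fixed before the data were examined. The floored values and the intervals over mice were added to the tests of cell type shares after their first result, and with the latter the equal loss of cell types came to be read as open.

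A pair of signals appeared outside the main comparison. Skeletal muscle genes on WT 2 lay 9.14 above the mean of the other arrays on the log2 scale, and 18S rRNA control probe sets were 0.803 higher in KO than in WT.

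Cell cycle genes were lower in KO. The difference of the list mean was -1.75 unadjusted and -1.06 after adjustment for 18S signal, with a 95% interval of -1.99 to -0.13. This interval excludes 0, as predicted if carry-over of rRNA were not the whole source. However, 18S signal was higher on every KO array than on every WT array, so adjustment on 6 arrays cannot separate it from genotype. Carry-over of rRNA therefore stays open. RNA integrity stays open, because adjustment for the pyruvate carboxylase measure gave -1.57 with an interval of -3.85 to 0.70 on 6 arrays. A lower share of non-parenchymal cells that divide at an unchanged rate also stays open: the cell cycle median lay -1.12 from the macrophage median (bootstrap interval over genes -1.41 to -0.03), but -0.34 with values floored at 4 (-1.29 to 0.11), while the floored list means differed by -0.59 with an interval over mice of -0.91 to -0.27. Less cell division in KO livers may account for the difference too, as a hypothesis that these arrays cannot separate from the explanations left open.

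Macrophage, endothelial and stellate markers were lower in KO. An equal loss of all these cells stays open: the macrophage median lay -0.59 from the endothelial median (bootstrap interval over genes -0.88 to -0.40), but resampling genes leaves out the spread between mice, and the interval of the difference in list means over the 6 mice, -1.24 to 0.05, holds 0. Carry-over of rRNA stays open for the macrophage markers, whose difference was -0.94 unadjusted and -0.37 after adjustment for 18S signal (95% interval -1.84 to 1.10). Fewer macrophages, or less of these transcripts per cell, could each give the pattern and were not told apart by a test.

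The muscle transcripts on WT 2 may come from skeletal muscle RNA in that sample. Of 26 further muscle genes detected on any array, 25 were over 2-fold higher on WT 2 than on every other array. This RNA is argued against as the source of the cell cycle difference, whose median without WT 2 was -2.132 (camera in limma, adjusted p = 1.16e-11). WT 2 had the lowest cell cycle list mean of the WT arrays, 7.201. Leaving it out was therefore bound to widen the difference of the list means. With an estimated correlation the cell cycle list did not pass even with all arrays (limma, adjusted p = 0.781). A biological origin of the muscle signal was not tested.

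The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 17 genes and the highest other 1, so 1 of the 10 gave as many. For genes changed at least 2-fold by the fitted difference, without bounds for dim genes, the real split gave 12 and the highest other 1, again 1 of the 10. For lists, 5 of the 10 gave as many as the real 8, and the highest other gave 12. The splits that joined KO 1 and KO 2 with a WT array gave 12, 9 and 12 lists.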

How the results depend on the processing

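Leaving out the genes private to WT 2, the genes with a single value on all arrays, or KO 3 and WT 2 together was chosen after the data were seen. The count of 17 called genes was 3 with no filter, 10 with a minimum of 6, 8 with a mean of at least 4, 11 with every probe set tested, 3 with the ordinary two-sample test and 3 without KO 3 and WT 2. The count of 12 at 2-fold was 2 with no filter, 6 with a mean of at least 4, 19 with values floored at 4, 2 with the ordinary test and 3 without KO 3 and WT 2. Leaving out 1 array gave 1 to 140 genes and 1 to 101 at 2-fold, the highest without KO 3; all 17 genes were among the 140. Both counts stayed within 1.5 times with the other alternatives, except the replicate block below and, at 2-fold only, the floored values above. The genes kept for the left-out arrays and the floored values were settled after first counts were seen. The causes were not tested, beyond the fewer arrays, or the other number of genes tested, that some alternatives bring.

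Lamtor2 lay between -1.225 and -1.166 with 1 array left out, at -0.721 with the mean of its probe sets, and at -1.199 without KO 3 and WT 2 (limma, adjusted p = 0.114, range over alternatives 0.00381 to 0.116). Replicate numbers did not pair the samples, with correlations of deviations of -0.086, -0.079 and -0.141. With the replicate block the counts were 0 and 0, and Lamtor2 stood at -1.191 (limma, adjusted p = 0.116).

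Of the 8 lists 0 passed with an estimated correlation (adjusted p = 0.781 for each) and 1 with fry, the cell cycle. The fry adjusted p in limma was 0.468 for acute-phase, 0.309 for interferon, 0.243 for stellate, and 0.208 for MHC class II, male-biased, macrophage and endothelial genes. With 1 array left out 7 to 11 lists passed. The camera adjusted p in limma then ran from 1.61e-09 to 0.0317 for acute-phase, 0.000126 to 0.397 for interferon, the highest without WT 2, 0.000252 to 0.00824 for MHC class II, 2.23e-19 to 1.16e-11 for cell cycle, 2.98e-06 to 0.00539 for male-biased, 3.01e-12 to 0.000256 for macrophage, 3.7e-06 to 0.035 for stellate and 2.05e-05 to 0.0116 for endothelial genes. With the mean of a gene's probe sets, 2 of the named genes that were not called changed sign, Sel1l to 0.205 and Car3 to -0.147. Genes near the lowest value limit what the arrays resolve.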

Other observations

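All tests of the Wnt and pericentral lists were chosen after the data were seen, and how to read them was changed after the results were known. The test of the genes near Lamtor2 was set beforehand, but its interval was added, and its result read as undecided, after the p was seen.

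Feedback targets of Wnt signalling, which marks the liver zone around the central vein, were lower in KO. All 8 measured members had lower values, with a median of -0.82, and 1 of them fell when adjusted over the list alone. Axin2, a scaffold that restrains the pathway, differed by -1.46, Rnf43 by -1.03 and Nkd1 by -0.99. List means were 6.64 to 6.89 on the KO arrays and 7.35 to 7.98 on the WT arrays. Between the same groups the 18S rRNA controls were 0.803 higher in KO, the pyruvate carboxylase 3 prime minus 5 prime measure differed by -0.95, and macrophage and endothelial markers had medians of -0.89 and -0.30. Camera in limma gave p = 0.00012, and p = 0.068 with an estimated correlation, which describes the list and does not test a reason for it, since the list was chosen after the data were seen. Pericentral metabolic genes, which less Wnt signalling could also lower, had a median of -0.16 over 14 genes (camera in limma, p = 0.028, and p = 0.29 with an estimated correlation), and their list means overlapped between the groups, so less Wnt signalling stays open as a hypothesis.

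Strain variants carried along with the targeted locus were tested on the 50 measured genes nearest to Lamtor2. Of these 14% had an unadjusted p under 0.05, against 14.4% of the other genes (one-sided Fisher exact p = 0.6, 95% interval of the odds ratio 0.37 to 2.17), which leaves a few such genes possible.

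The Y-linked genes Eif2s3y, Kdm5d and Uty were detected on all 6 arrays, with Eif2s3y between 8.84 and 9.05. Of the 64 control probe sets, 16 were higher on every KO array than on every WT array and 2 were lower, where chance gives 10% for both directions together. Many of these probe sets measure the same transcript, so they are not independent. Among all genes tested, groups did not overlap for 20.53%. Several of the 16 were poly-A spike-ins, such as a DapX probe set at 10.30 in KO and 10.03 in WT. Spike-ins do not come from the liver, while the 18S rRNA probe sets, also among the 16, measure RNA of the sample. The source of these differences was not tested. WT 2 had 173 genes over 2-fold above all other arrays, against 11 to 25 on each of the others.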
